A study of Mus musculus with 2 samples.

How the data were processed

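The data were 2 single-cell RNA libraries of mouse cells, 1 from gastrocnemius muscle and 1 from lung. Per the labels' protocols tissue was minced, digested with Liberase TL and DNase I, freed of red cells by lysis and passed over CD45 magnetic beads, and libraries were made with the 10x Genomics 5' v2 kit and sequenced on an Illumina NovaSeq instrument. Per the labels the mice were TB mice of the CAC model. The number of mice behind each library and any treatment of these mice are not given there, and the meaning of both short names was not assumed. The series design also names muscle RNA sequencing under IgG, anti-PD-L1 and anti-CD8a, which was not analysed here.

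The deposited values were raw UMI counts per gene and barcode, made with Cell Ranger 7.0.1 on genome build GRCm39 per the submitters' processing notes. The annotation release, the counting of introns and the cell calling settings are not stated there. No deposited barcode held fewer than 500 UMIs. The reference genome at hand was of another build, so gene names were taken as deposited and no coordinates were used. Of the fixed genes Znf683, Tcrg-C1 and Cd163l1 were not found under those names and were left out. Some members of the fixed lists are not reported by name because they were withheld.

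Depth was 14056163 UMIs over 5547 barcodes in muscle and 34751225 UMIs over 8481 barcodes in lung. Cells were kept with at least 200 genes and at most 10% of UMIs from 37 mitochondrial genes, which left 2243 muscle and 8194 lung cells. The labels do not say that doublets were removed, so cells were scored by the share of simulated doublets (2 per cell) among their neighbours. The top 0.8% per 1000 barcodes was removed, 100 muscle cells (4.46%) and 556 lung cells (6.79%). Kept cells held 8693553 UMIs in muscle and 29055054 in lung. The precision this depth gave is carried by the interval beside each value, for Ctsl in neutrophil-like cells from 308 to 337 CPM around 322 CPM in lung (1967 counts) and from 30.9 to 104 CPM around 59.8 CPM in muscle (12 counts).

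Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and logged, 2000 variable genes were taken among genes seen in at least 20 cells, values were clipped at 10, and 30 principal components, 15 neighbours, a shared-neighbour graph with Jaccard weights of at least 0.066667 and Leiden clustering at resolution 1.0 with seed 1 gave 39 clusters. Mitochondrial, ribosomal, immunoglobulin and T cell receptor variable, haemoglobin, myofibre and lung epithelium genes were left out of the variable genes. A cluster took the class with the highest mean log2 fold over all other cells across its fixed markers, if at least 3 markers were 2-fold up in 10% of cells and the mean was above 0.5. A cluster with a median depth under 0.333 of its library and no own marker among its top 10 genes stayed unnamed. Names are therefore likenesses to marker lists. T-like and NK-like cells were clustered again by the same steps, which was chosen after the data were seen.

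Levels are CPM, the summed counts of a gene over the summed counts of all genes in a class and library, with exact Poisson 95% intervals. Shares of cells have exact Clopper-Pearson intervals, and muscle over lung ratios have exact conditional binomial intervals. With 1 library per tissue there was no test between tissues. A gene was called apart by size when its ratio was at least 4 either way, its interval excluded 2 and the higher library held at least 30 counts. Where a library had no count, the ratio was bounded against a floor of 3 counts. Shares of positive cells were also taken after thinning each cell to 1000 UMIs, or 500 where the class median was under 1000, with shallower cells left out. Free RNA was read from the level of a gene in lung B-like, T-like or NK-like cells.

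Gene lists were fixed before the data were examined. They covered cathepsins, cathepsin inhibitors, lysosome, checkpoint ligands and receptors, cytotoxic effectors, naive and central memory T cell, tissue-resident T cell, interferon response, MHC class II, resident macrophage, lipid-associated macrophage, inflammatory cytokines and chemokines, cachexia-linked secreted factors, hypoxia and glycolysis, immature neutrophil granule, chemokine receptors and egress, cell cycle and dissociation stress genes. Lists for other cell types covered myofibre, lung epithelium, fibroblast, endothelium and erythroid genes. A list value is the median log2 ratio of members with at least 10 counts over both libraries, given where at least 3 were measured. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, is a description of these 2 libraries. A list was called higher or lower when that percentile lay in the outer 5% and the interval of the median over its members excluded 0. Members whose bound held no information entered the median as 0.

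The rule for named genes was also set before the data were examined. It took the 3 largest and 3 smallest ratios per class among genes apart by size. Such a gene needed at least 50 CPM in the higher library and at least 0.5 times the highest CPM of any other class there. It could not have a ratio of at least 2 toward the same tissue in every class. It also took Ctsl and the other cathepsins, Cd274, Pdcd1, Cd8a and Pdcd1lg2, and from each list the most abundant members and the extreme ratios with at least 30 counts. For a described cluster it took the 5 top genes by fold with at least 25% of cells positive. Classes needed 100 cells in each library by the plan and 30 by the choice made after the data were seen. Other genes named below, such as Xist, the Y-linked genes, Ptprc as a gate check, cluster markers and the subset markers of T-like and NK-like cells, were chosen after their values were seen.

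Alternatives set in advance were a minimum of 500 genes, a mitochondrial limit of 5%, no doublet removal or removal at double the share, Leiden resolutions 0.5 and 2.0, libraries clustered alone, TMM scaling with edgeR, thinning, subtraction of the B-like level, a ratio of at least 2, no minimum count and list members with at least 50 counts. Chosen after the data were seen were limits of 25% and none, totals without mitochondrial and rRNA-like genes (Rn18s, Mir6236, Cmss1 and Cdk8), 1 cluster per class, each gene without its highest cell, and the minimum of 30 cells. The ratio and list steps were tested on simulated data with 200 altered genes per class among 55416. The altered genes were drawn from the 1065 to 3051 genes per class with at least 30 expected counts in each library, so recovery holds for such genes only. All 8-fold differences and from 45.1% to 60.5% of 4-fold differences were called, none in the wrong direction, and 1 unaltered gene was called in macrophage-like cells and none in the other classes. Of 200 unaltered lists per class from 4% to 8% fell in the outer 5% of percentiles. The simulated class sums carried Poisson counting error only, with no variation between cells or mix of clusters. They therefore cannot show how often calls carried by few cells or by cluster mix arise in the real counts. A 4-fold difference also lies at the rule's own minimum ratio. Work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.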

Results

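Single-cell 5' RNA sequencing counted UMIs of 55416 genes in cells selected with CD45 magnetic beads from gastrocnemius muscle and from lung. Per the labels both libraries came from TB mice of the CAC mouse model, and neither carries a treatment label. There was 1 library per tissue and no replicate, so no test of a tissue difference was possible. Intervals in brackets are exact 95% intervals and hold counting error only. The muscle library held 5547 barcodes and 14056163 UMIs with a median of 1716 UMIs and 654 genes per barcode. The lung library held 8481 barcodes and 34751225 UMIs, with medians of 2252 UMIs and 1027 genes. Mitochondrial genes took 18.7% of muscle UMIs and 2.01% of lung UMIs, and 3301 muscle barcodes (59.5%) against 273 lung barcodes (3.22%) were over the limit of 10%. After filters and doublet removal 2143 muscle cells (median 3057 UMIs) and 7638 lung cells (median 2130 UMIs) were kept. Rn18s, an rRNA-like gene, took 5.24% of muscle and 6.93% of lung UMIs.

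Leukocyte classes made up 328 of 2143 kept muscle cells (15.3%, 13.8 to 16.9) and 7095 of 7638 kept lung cells (92.9%, 92.3 to 93.5). The lung leukocytes took in a shallow cluster of 966 alveolar macrophage-like lung cells and another of 263 neutrophil-like lung cells. Their medians were 821 and 717 UMIs, with Rn18s at 175138 and 209516 CPM and Ptprc at 137.7 and 171.8 CPM. Whether these were intact leukocytes was not tested. Endothelial-like cells were the largest muscle class with 1212 cells (56.6%, 54.4 to 58.7), followed by fibroblast-like cells (12.4%, 11 to 13.8) and pericyte- or smooth muscle-like cells (9.61%, 8.40 to 10.9). Schwann-like cells held 58 muscle cells (2.71%) and satellite-like cells, the Pax7-bearing stem cells of muscle, held 53 (2.47%). Neither class was found in lung, where a floor of 3 cells set a limit of 0.0393%. In lung the endothelial-like class held 111 cells (1.45%, 1.20 to 1.75) and the epithelial-like class 384 cells (5.03%, 4.55 to 5.54). Ptprc, which encodes CD45, stood at 554 CPM (525 to 584) in muscle leukocytes and 535 CPM (526 to 544) in lung leukocytes. Its level was 3.60 CPM (2.25 to 5.44) in the other named muscle classes and 9.79 CPM (6.65 to 13.9) in those of lung. The shares describe cells that passed CD45 beads, a deposited minimum of 500 UMIs per barcode and libraries of unequal depth, so they are not shares of the tissues. Under the alternatives tried the leukocyte share ran from 10.3% to 21.9% in muscle and from 76.6% to 92.9% in lung.

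Among muscle leukocytes conventional DC2-like cells, which present antigen to CD4 T cells, were the largest class with 120 cells (36.6% of leukocytes, 31.4 to 42.1), against 77 lung cells (1.09%, 0.857 to 1.35). The class was 1 cluster with Lyz1, Retnla, Cd209a, Cd209d and Fcrls as its top genes. Of its markers the lectin Mgl2 stood at 780.4 CPM against 76.3 CPM in all other cells, and the DC growth factor receptor Flt3 at 10.01 against 14.4 CPM. Resident macrophage genes were also read in its muscle cells, with a list median of 2.45 over lung. Classical monocyte-like cells held 71 muscle cells (21.6%, 17.3 to 26.5) and 703 lung cells (9.91%, 9.22 to 10.6), from 2 clusters mixed differently by library. The cluster with Ccl2, Ccl24, Vcan, Gm9733 and Arg1 as top genes held 33 muscle and 555 lung cells, and the cluster with Cacna1d, Tlr8, Nrg1, F13a1 and Slc8a1 held 38 and 148. The monocyte marker Plac8 stood at 598 CPM in the former and 24.1 CPM in the latter, and Malat1, a nuclear RNA, at 1901 and 9225 CPM. Macrophage-like cells held 33 muscle cells (10.1%, 7.03 to 13.8) and 85 lung cells (1.20%, 0.958 to 1.48). Neutrophil-like cells, the first phagocytes to enter inflamed tissue, were the largest lung class with 2793 cells (39.4%, 38.2 to 40.5) and held 57 muscle cells (17.4%, 13.4 to 21.9). Of the lung cells 452 lay in a cluster that passed the naming rule narrowly, with 3 markers and none among its top 10 genes, where Cd274 stood at 1179 CPM, Ccl3 at 7907 CPM and Ctsl at 489.99 CPM. Retnlg and Cxcr2, neutrophil markers, stood at 109 and 58.2 CPM there, against 249.6 and 67.0 CPM in other cells, while S100a8 and Csf3r stood at 7019 and 616 CPM, against 2646 and 220 CPM. Alveolar macrophage-like cells made up 21.4% of lung leukocytes (20.5 to 22.4) and took in 20 muscle cells. In this class 966 lung and 11 muscle cells lay in a shallow cluster (median 821 UMIs) with Atpif1, Ndufc1, Rn18s, Prdx1 and Fabp5 as top genes, which passed the naming rule with 3 markers. Its Ctsl level was 387 CPM, against 663 CPM in the deeper cluster of the class. Of the class markers Siglecf stood at 10.9 CPM in the shallow and 16.6 CPM in the deeper cluster, against 26.2 and 27.5 CPM in other cells. Car4 stood at 137 against 192 CPM in the shallow cluster and 254 against 178 CPM in the deeper. Ear2 and Chil3 were above other cells in both, Chil3 at 1984 against 953 CPM and 3686 against 463 CPM.

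Lymphoid classes were rare in muscle. T-like, NK-like, B-like and plasma-like cells together held 15 muscle cells (4.57% of leukocytes, 2.58 to 7.43) and 1675 lung cells (23.6%, 22.6 to 24.6). B-like cells held 687 lung cells (9.68%) and 4 muscle cells, T-like cells 677 and 6, and NK-like cells 258 and 5. The NK-like class was 1 cluster with Cd8a in 49.05% of its cells and the NK receptor Klre1 in 30.04%. Its count and the T-like count are therefore not counts of NK cells and T cells. Of the 11 muscle T-like and NK-like cells 5 lay in a sub-cluster of 16 cells with 1 count of Cd3e, the T cell receptor subunit, and markers of group 2 innate lymphoid cells. A further 4 lay in a sub-cluster with Cd3e at 486 CPM and Cd8a at 347 CPM, and none lay in the sub-cluster of 50 lung cells with NK receptors and no count of Cd3e. Migratory DC-like cells, which carry antigen to lymph nodes, held 143 lung cells (2.02%) and none in muscle, and plasma-like cells held 53 and none, with a muscle limit of 0.915% for each. Conventional DC1-like cells, which cross-present antigen to CD8 T cells, held 12 muscle cells (3.66%) and 99 lung cells (1.40%). Class borders within lung myeloid cells moved with the settings. The macrophage-like share of lung leukocytes ran up to 19.6%, the alveolar macrophage-like share from 3.20% to 29.1% and the cDC2-like share from 0.159% to 5.43%, while the muscle cDC2-like share ran from 32.4% to 52.6%.

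**Figure D1:**
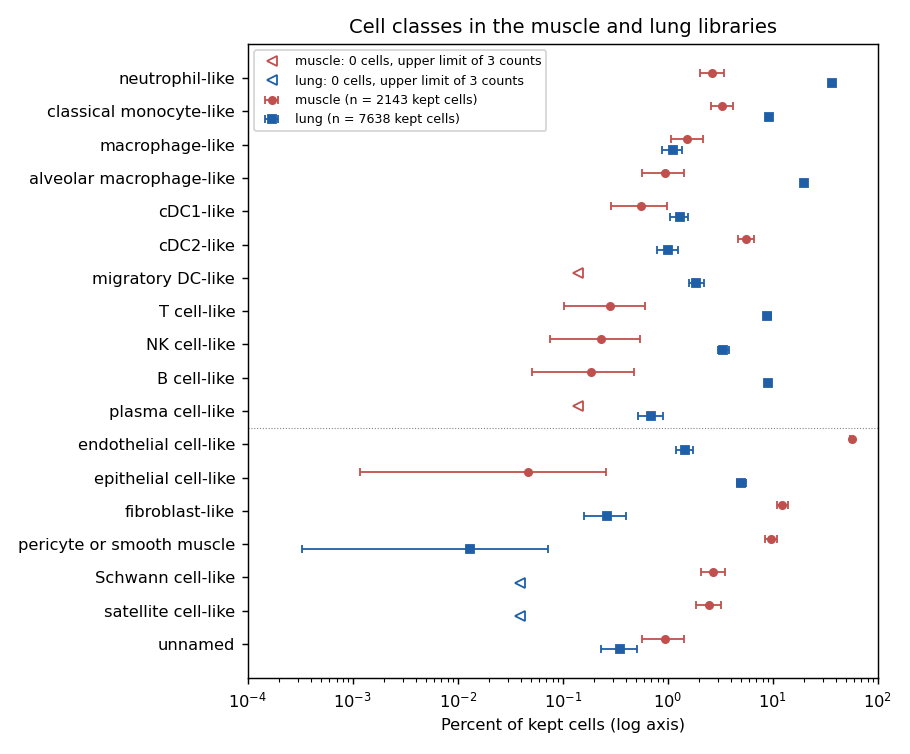
Percent of kept cells (log axis) in each class for muscle (circles, n = 2143 cells) and lung (squares, n = 7638 cells), with bars for exact 95% intervals, open triangles for the limit of 3 cells where none were found, and a dotted line between leukocytes and other classes. Endothelial-like cells led in muscle at 56.6% and neutrophil-like cells in lung at 36.6%.

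Ctsl, the lysosomal cysteine protease cathepsin L, was highest in macrophage-like and fibroblast-like cells under the main settings. Macrophage-like cells held 1099 CPM in muscle (965 to 1246) and 1297 CPM in lung (1202 to 1396), and muscle fibroblast-like cells held 1008 CPM (953 to 1065). The fibroblast-like level pooled clusters at 1123 and 1073 CPM with a cluster of 100 muscle cells at 87.5 CPM. Muscle satellite-like cells stood at 755.5 CPM (631 to 898), muscle endothelial-like cells at 492 CPM (471 to 515), lung epithelial-like cells at 553 CPM (525 to 583) and lung alveolar macrophage-like cells at 627 CPM (609 to 646). The epithelial-like level pooled a cluster of 59 cells of median 31375 UMIs at 611 CPM with a cluster of 325 lung cells and 1 muscle cell of median 751.5 UMIs at 325 CPM. Schwann-like cells held 211 CPM (146 to 295) and pericyte- or smooth muscle-like cells 158 CPM (128 to 193). Lung B-like cells, a class with little known cathepsin L, stood at 42.7 CPM (33.4 to 53.7), and lung T-like and NK-like cells at 57.3 and 40.1 CPM. Pooled leukocytes held 196 CPM in muscle (179 to 215) and 397 CPM in lung (389.7 to 405), while pooled other classes held 564 CPM (545 to 583) and 553 CPM (527 to 579). Clustering, filters and doublet removal took the lung macrophage-like level as low as 524 CPM, totals without mitochondrial and rRNA-like genes took it to 1424 CPM, and clustering moved the muscle endothelial-like level from 225 to 743 CPM. Over the alternatives the lung epithelial-like level ran from 237 to 1679 CPM, above every macrophage-like and fibroblast-like value. The pericyte- or smooth muscle-like level ran from 34.7 to 538 CPM, and both were highest with TMM scaling. Their TMM factors, 0.330 in lung and 0.293 in muscle, were set against the other library of the same class. That library held 1 muscle epithelial-like cell (1964 UMIs) and 1 lung pericyte- or smooth muscle-like cell (871 UMIs). The values of 1679 and 538 CPM therefore rested on scaling against 1 cell and cannot rank these classes.

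Between the tissues Ctsl was lower in muscle than in lung in neutrophil-like and monocyte-like cells. Neutrophil-like cells held 59.8 CPM in muscle (30.9 to 104, 12 counts in 57 cells) and 322 CPM in lung (308 to 337), a log2 ratio of −2.43 (−3.39 to −1.62). Monocyte-like cells held 207.5 against 575 CPM, a log2 ratio of −1.47 (−1.76 to −1.19), and cDC2-like cells 59.7 against 106.5 CPM (−0.84, −1.38 to −0.28). In macrophage-like cells the log2 ratio was −0.24 (−0.45 to −0.03) and in endothelial-like cells 0.15 (−0.11 to 0.43). Ctsl was detected in 15.8% of muscle and 37.1% of lung neutrophil-like cells at median depths of 3109 and 1905 UMIs, and in 7.14% and 21.9% after thinning to 1000 UMIs. For monocyte-like cells the values were 32.4% and 71.0%, and 8.45% and 33.5% after thinning. Lung B-like cells, at a median of 2032 UMIs, were positive in 8.73% and in 3.19% after thinning. The ratio ran from −2.68 to −1.96 in neutrophil-like, from −3.42 to −1.24 in monocyte-like and from −0.82 to 0.58 in macrophage-like cells over the alternatives, so its direction turned in the last class.

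Other cathepsins differed by class. Ctsb, a lysosomal cysteine protease, was higher in muscle macrophage-like cells (5838 against 3553 CPM, log2 ratio 0.72, 0.61 to 0.82) and lower in muscle neutrophil-like cells (149.5 against 471 CPM, −1.65, −2.22 to −1.14). Ctss, which trims the MHC class II invariant chain, stood at 44.9 against 266.5 CPM in neutrophil-like cells (−2.57, −3.70 to −1.64), at 2955 against 2512 CPM in macrophage-like cells (0.23) and at 1192 against 1018 CPM in cDC2-like cells (0.23). Lung B-like and NK-like cells held Ctss at 410 and 169 CPM. Ctsd, a lysosomal aspartic protease, was lower in muscle monocyte-like cells (348 against 1002 CPM, −1.52, −1.75 to −1.31) and stood at 247.5 against 118 CPM in cDC2-like cells (1.07, 0.64 to 1.52). Ctsc, which activates granule serine proteases, stood at 518 against 270 CPM in cDC2-like cells (0.94, 0.66 to 1.24), and Ctsz at 324 against 319 CPM in neutrophil-like cells (0.02, −0.36 to 0.38). No median of the 14 listed cathepsins was called. The median log2 ratio was 0.44 in cDC2-like cells (98.55th percentile of matched random lists, 10 measured), −0.40 in neutrophil-like cells (15.95th, 12 measured, 2 apart by size), −0.20 in monocyte-like (38.1st), −0.17 in macrophage-like (46.4th) and −0.39 in endothelial-like cells (8.27th). Over the alternatives the cDC2-like median ran from −0.55 to 0.72, Ctsd there from −0.99 to 1.67 and Ctsc from −0.55 to 1.22, so all 3 turned direction. Neutrophil-like Ctsb came as near to 0 as −0.37, within 1 cluster.

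Lysosome genes as a list were lower in muscle neutrophil-like cells, and cathepsin inhibitors had a negative median there that was not called. The inhibitor median was −1.27 (2.11th percentile, 4 measured, none apart by size), with Cstb, cystatin B, at 259 against 1010 CPM (−1.96, −2.39 to −1.57) and Cst3, the secreted cystatin C, at 827 against 1455 CPM (−0.81, −1.04 to −0.59). It was −0.51 in cDC2-like (10.5th), −0.14 in monocyte-like (36.7th), −0.05 in macrophage-like (65.2nd) and −0.26 in endothelial-like cells (15.1st), where Cst3 stood at 1599 against 637 CPM (1.33, 1.11 to 1.56). The lysosome median was −1.15 in neutrophil-like cells (0.300th percentile, 18 measured, 3 apart), with Scarb2, the sorting receptor of glucocerebrosidase, at −3.75 (−6.80 to −1.89) and Psap, the saposin precursor, at 354 against 757 CPM (−1.10, −1.46 to −0.76). In macrophage-like cells it was 0.14 (97.9th percentile). In monocyte-like cells it was −0.07 (59.8th), in cDC2-like cells −0.06 (71.1st) and in endothelial-like cells −0.56 (0.520th), with the tetraspanin Cd63 at 58.1 against 337 CPM (−2.54, −2.89 to −2.17). Over the alternatives the neutrophil-like lysosome median came as near to 0 as −0.09, while the inhibitor median stayed between −1.72 and −0.54.

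**Figure D2:**
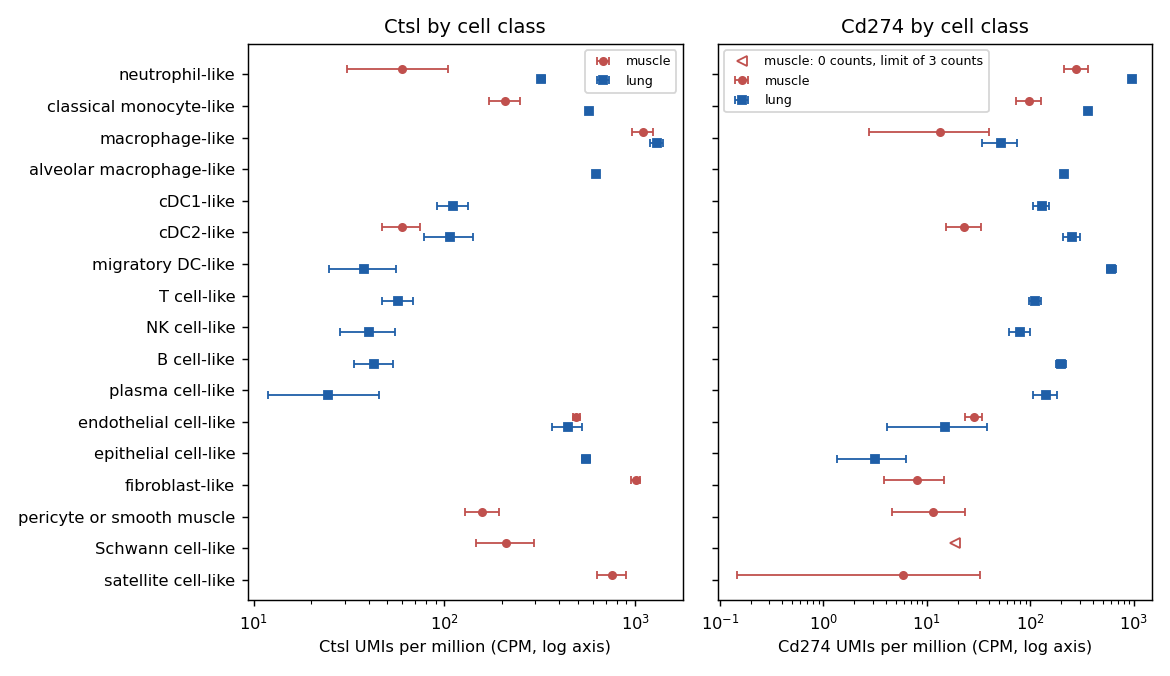
Ctsl and Cd274 in CPM (log axes) for each class with at least 30 cells in a library, muscle and lung, with bars for exact Poisson 95% intervals and open triangles at the floor of 3 counts. Ctsl was highest in lung macrophage-like cells (1297 CPM) and Cd274 in lung neutrophil-like cells (949.8 CPM).

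Cd274, which encodes PD-L1, was highest in lung neutrophil-like cells (949.8 CPM, 925 to 975) and lung migratory DC-like cells (605 CPM, 548 to 666). It was lower in muscle in every compared leukocyte class. The cells under the cDC2-like name also differed by library, with Lyz1 at 2559 CPM in muscle and 6.80 CPM in lung. A mix of cells was thus not separated from the tissue difference there. Neutrophil-like cells held 279 CPM in muscle (211 to 362; log2 ratio −1.77, −2.17 to −1.39), monocyte-like cells 97.1 against 361 CPM (−1.90, −2.33 to −1.49) and cDC2-like cells 23.1 against 252 CPM (−3.45, −4.09 to −2.85), the last apart by size. Macrophage-like cells held 13.5 against 51.8 CPM from 3 muscle counts (−1.94, −4.30 to −0.24), and endothelial-like cells 28.6 against 14.99 CPM (0.93, −0.47 to 2.83). Cd274 was detected in 35.1% of muscle and 54.1% of lung neutrophil-like cells, and in 21.4% and 42.4% after thinning, against 1.82% and 0.521% of lung epithelial-like cells, which had a median of 859 UMIs and were thinned to 500. Pooled leukocytes held 60.6 CPM in muscle (51.3 to 71.0) and 405 CPM in lung (397 to 413). Lung B-like, T-like and NK-like cells stood at 198, 112 and 79.2 CPM. The ratio ran from −1.95 to −1.31 in neutrophil-like, from −3.43 to −0.78 in monocyte-like and from −3.57 to −2.59 in cDC2-like cells over the alternatives that gave a ratio. Subtraction of the B-like level gave no ratio, since muscle held 4 B-like cells. It took the lung cDC2-like level from 252 to 53.4 CPM and the lung monocyte-like level from 361 to 163 CPM. Under it the cDC2-like difference was not shown to stay apart by size. Lung epithelial-like, fibroblast-like and endothelial-like cells, however, held Cd274 at only 3.18, 10.6 and 14.99 CPM. The B-like level was therefore not shown to be free RNA, and the subtraction cannot decide this.

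Pdcd1, the PD-1 receptor, stood at 1.20 CPM in muscle leukocytes (0.247 to 3.49, 3 counts) and 20.9 CPM in lung leukocytes (19.1 to 22.7), and Cd8a, the CD8 alpha chain, at 4.38 CPM (2.19 to 7.84) and 28.3 CPM (26.3 to 30.5). Pdcd1lg2, which encodes PD-L2, held 9.56 CPM in muscle leukocytes (6.13 to 14.2) and 72.7 CPM in lung leukocytes (69.5 to 76.1). Its log2 ratio was −3.97 (−6.26 to −2.42, 3 muscle counts) in monocyte-like, −2.62 (−4.90 to −1.07, 3 muscle counts) in neutrophil-like and −2.44 (−3.64 to −1.33) in cDC2-like cells. Of the CD28 ligands, Cd80 was lower in muscle neutrophil-like (324 against 726 CPM, −1.16, −1.54 to −0.81), monocyte-like (120 against 310.0 CPM, −1.37) and cDC2-like cells (86.0 against 211 CPM, −1.29). Cd86 stood at 499 against 409 CPM in monocyte-like (0.29, 0.09 to 0.47) and 259 against 238 CPM in cDC2-like cells (0.12, −0.20 to 0.45). The median of the 10 checkpoint ligands and receptors was −2.23 in cDC2-like (7 measured), −1.63 in monocyte-like (6), −1.72 in neutrophil-like (6) and −0.68 in macrophage-like cells (4). None was called. The first 3 lay under the 1st percentile of matched random lists and the last at the 10.7th, and the endothelial-like median was 0 over 3 genes (59.55th). In monocyte-like cells it came as near to 0 as −0.12 under the alternatives.

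Gene by gene, the planned minimum of 100 cells in both libraries left only endothelial-like cells, so the minimum of 30 cells that also let in cDC2-like, monocyte-like, neutrophil-like and macrophage-like cells was chosen after the data were seen. In endothelial-like cells 261 genes were apart by size toward muscle and 91 toward lung, of 9270 evaluable. Counts toward muscle and lung were 64 and 44 of 4703 in cDC2-like, 64 and 94 of 8805 in monocyte-like, 43 and 155 of 8502 in neutrophil-like and 17 and 58 of 3002 in macrophage-like cells. Within 1 cluster the counts were 9 and 32 in neutrophil-like, 56 and 173 in monocyte-like and 123 and 31 in endothelial-like cells. The further conditions for a named gene were met by 26 and 77 in neutrophil-like and 11 and 22 in macrophage-like cells. Genes with a ratio of at least 2 toward muscle in every compared class, and apart by size in any of them, numbered 15. The most abundant were mt-Rnr2, a mitochondrial rRNA (ratios 2.56 to 6.16), Fabp4, a fatty acid carrier (2.18 to 6.58), and Cdk8 (2.94 to 14.1), treated as rRNA-like in an alternative. Fabp4 stood at 10414 CPM in muscle endothelial-like cells and from 24.7 to 93.3 CPM in the 4 muscle leukocyte classes, so free RNA as its source in leukocytes was not excluded. Toward lung the same rule gave 14 genes. The most abundant were Basp1 (ratios 0.0360 to 0.304), Arg1, the arginase of alternatively activated myeloid cells (from 0.00972 or lower to 0.0893 or lower, both against the floor of 3 counts), and AA467197 (0.0123 to 0.190). Arg1 was also read in lung NK-like cells at 81.2 CPM and lung B-like cells at 74.2 CPM.

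In neutrophil-like cells the genes named toward muscle rested on few cells and on the mix of clusters. Mmp8, the neutrophil collagenase, stood at 603 against 49.5 CPM (log2 ratio 3.61, 3.29 to 3.92), read in 20 of 57 muscle cells. Ngp, a granule protein of maturing neutrophils, stood at 4172 against 365 CPM (3.52, 3.40 to 3.63), with 64.3% of its counts in 1 cell, and Ly6a2 at 164 against 12.6 CPM (3.70, 3.07 to 4.31) in 5 cells. Toward lung stood Med12l at 4.98 against 339 CPM (−6.09, −11.39 to −3.61), Ltc4s, the leukotriene C4 synthase, at 4.98 against 169.8 CPM (−5.09, −10.40 to −2.61) and Rhoh at 9.97 against 277 CPM (−4.80, −7.84 to −2.94). Of the 57 muscle cells 42 lay in cluster 9, which held 350 of 2793 lung cells and had Retnlg, Lcn2, Asprv1, S100a9 and Ifitm1 as its top genes. Med12l was a top gene, at 1004 CPM, of a cluster of 278 lung and 5 muscle cells. The mix of clusters was thus not separated from the lung side either. The immature neutrophil granule list had a median of 2.73 (100.0th percentile, 7 measured, 5 apart, not called), with Lcn2, a siderophore-binding granule protein, at 4516 against 802 CPM (2.49, 2.39 to 2.60), Camp, the cathelicidin, at 3449 against 419.6 CPM in 3 muscle cells (3.04, 2.92 to 3.16) and Ltf, lactoferrin, at 1411 against 213 CPM (2.73, 2.54 to 2.91). Within cluster 9 the median was 1.06, and Mmp8, Ngp and Ly6a2, at 1.79, 1.30 and 1.45, were not apart by size.

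The same list had a median of 2.73 in monocyte-like cells (100.0th percentile, 7 measured), where every muscle count of Camp came from 1 cell, and the median ran from −2.22 to 3.92 over the alternatives. Monocyte-like genes toward muscle were Frmd5 at 194 against 0.666 CPM (8.19) in 7 of 71 muscle cells with 56.9% of counts in 1 cell, Camp at 387 against 2.00 CPM (7.60, 6.64 to 8.75) and Kcnq1, a potassium channel, at 139 against 0.888 CPM (7.29). Toward lung stood Saa3, an acute phase serum amyloid, at 1.90 against 369 CPM (−7.60, −12.90 to −5.12), Spp1, the matrix protein osteopontin, at 9.52 against 1687 CPM (−7.47, −9.09 to −6.25), and Inhba, the activin A subunit, at 1.90 against 169 CPM (−6.47, −11.78 to −3.99). Spp1 was read in 322 of 703 lung cells and Saa3 in 63. Lung T-like cells held Spp1 at 94.7 CPM. Over the alternatives Saa3 and Inhba came as near to 0 as −1.51 and −1.78, and Spp1 as −4.98.

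In cDC2-like cells Lyz1, a lysozyme, stood at 2559 CPM in muscle and 6.80 CPM in lung (8.56, 7.01 to 10.83), read in 69 of 120 muscle cells. Mucl1 stood at 321 against 2.27 CPM (7.14) with 48.6% of counts in 1 cell, and Cd226, an activating adhesion receptor, at 150.4 against 4.53 CPM (5.05, 3.18 to 8.11). Toward lung stood Plet1 at 3.18 against 326 CPM (−6.68, −8.58 to −5.29), Enah, an actin regulator, at 3.18 against 111 CPM (−5.12) and Spint1, a serine protease inhibitor, at 13.5 against 136 CPM (−3.33, −4.20 to −2.53). With Lyz1 and Plet1 this far apart, different cells under the cDC2-like name were not separated from tissue in any ratio of the class. The 1-cluster setting gave no value for this class. Macrophage-like genes toward muscle were Slamf7, a SLAM family receptor, at 139.6 against 7.40 CPM (4.24, 2.74 to 6.20), Fxyd2, a sodium pump subunit, at 139.6 against 16.6 CPM (3.07) and Gpnmb, a marker of lipid-laden macrophages, at 819.8 against 116.5 CPM (2.81, 2.39 to 3.25). Toward lung stood Nrg1, the growth factor neuregulin 1, at 4.50 against 213 CPM (−5.56, −10.88 to −3.05), Ccl8, a monocyte chemokine, at 99.1 against 3558 CPM (−5.17, −5.84 to −4.56), and Saa3 with no muscle count against 501 CPM (log2 ratio −5.21 or lower, against the floor of 3 counts). Mucl1 and Cd226 came down to 2.00 and 1.39 and Ccl8 to −1.92 under some alternatives.

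Endothelial-like genes toward muscle were Timp4, a metalloproteinase inhibitor, at 1034 against 3.75 CPM (8.11, 5.63 to 13.41) in 752 of 1212 cells, Rasgrf2 at 327 against 3.75 CPM (6.45, 3.97 to 11.75) and Lnx1, a ubiquitin ligase, at 545 against 7.50 CPM (6.18, 4.33 to 9.23). Genes toward lung rested on few cells. Adgrl3 stood at 285 CPM in lung (−9.13, −12.20 to −7.22), with 60.5% of counts in 1 cell, the sodium channel subunit Scn3b at 112 CPM (−7.78) and the channel Scn7a at 161 CPM (−7.72), both with over 70% of counts in 1 cell. The lung class rested on 111 cells of median 741 UMIs, of which 92 lay in a cluster with 35 muscle cells. That cluster had Gng11, Mgp, Serping1, Bgn and Selenow as top genes, and Pecam1 at 277 CPM in 22.8% of cells, against 180.5 CPM in other cells. It had no endothelial marker among its top 10 genes, and neither had any other endothelial-like cluster. Most muscle endothelial-like clusters held few or no lung cells. Timp4 ran from 2.31 to 8.71 and Adgrl3 from −10.09 to −1.91 over the alternatives. Within 1 cluster, which was this cluster of 35 muscle and 92 lung cells, Rasgrf2 came to 0 and Scn3b to −1.42. Neither these nor Timp4, Adgrl3 and Scn7a were apart by size there. The cluster held 35 of 1212 muscle cells, with a median of 853 UMIs over both libraries and Rn18s at 140336 CPM. A bound without information is also set to 0. The cluster therefore cannot decide whether the differences toward muscle hold within a cluster.

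Hypoxia and glycolysis genes were lower in muscle in all 4 compared leukocyte classes. The list median was −1.56 in monocyte-like (under the 1st percentile, 12 measured, 3 apart), −1.46 in macrophage-like (1 apart), −1.26 in neutrophil-like (0.25th, 3 apart) and −0.71 in cDC2-like cells (0.150th, none apart), against −0.15 in endothelial-like cells (12th). Ero1a, an endoplasmic reticulum oxidase induced by HIF-1, stood at 49.5 against 519.6 CPM in monocyte-like (−3.39, −4.01 to −2.84), 105 against 657.5 CPM in neutrophil-like (−2.65, −3.34 to −2.04) and 18.0 against 92.5 CPM in macrophage-like cells (−2.36, −4.29 to −0.91). Hif1a, the oxygen-regulated transcription factor, stood at 246 against 712 CPM in monocyte-like (−1.54, −1.80 to −1.28), 81.1 against 387 CPM in macrophage-like (−2.25, −3.04 to −1.56) and 108 against 261 CPM in cDC2-like cells (−1.27, −1.64 to −0.90). Aldoa, the glycolytic aldolase, was nearer: 618 against 644 CPM in neutrophil-like (−0.06, −0.33 to 0.20), 444 against 633.5 CPM in monocyte-like (−0.51) and 401 against 313 CPM in macrophage-like cells (0.36, −0.03 to 0.74). Ero1a was read at 48.3 CPM in lung NK-like and 30.4 CPM in lung B-like cells. The medians of the 4 leukocyte classes kept their sign in all settings and ran from −2.70 to −1.49 in monocyte-like and from −2.18 to −0.44 in cDC2-like cells.

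Inflammatory cytokines and chemokines as a list were lower in muscle neutrophil-like cells (median −1.66, 12 measured, 3 apart). The medians of −1.25 in monocyte-like (3 apart), −0.98 in macrophage-like (5 apart) and 0.64 in cDC2-like cells (99.96th percentile, 2 apart) were not called, since their intervals over members included 0. In neutrophil-like cells Cxcl2, a neutrophil chemoattractant, stood at 6121 against 19589.6 CPM (−1.68, −1.76 to −1.60), Il1b, the pyrogenic interleukin 1 beta, at 7446 against 11889.5 CPM (−0.68), and the chemokines Ccl3 at 279 against 3224 CPM (−3.53, −3.94 to −3.15) and Ccl4 at 229 against 2047 CPM (−3.16, −3.61 to −2.74). Ccl3 in lung NK-like and T-like cells was 146 and 231 CPM. It stood at 574 CPM in cluster 9, which held 42 of the 57 muscle neutrophil-like cells, and from 1133 to 7907 CPM in the other neutrophil-like clusters. The mix of clusters was thus not separated from the tissue difference in Ccl3. In monocyte-like cells Ccl2, the CCR2 ligand, stood at 11.4 against 694 CPM (−5.92, −7.37 to −4.80) and Cxcl2 at 754 against 3158 CPM (−2.07, −2.21 to −1.92). In macrophage-like cells Il1b stood at 40.5 against 666 CPM (−4.04, −5.18 to −3.10) and Il6 at 4.50 against 111 CPM (−4.62, −9.95 to −2.09). Muscle cDC2-like cells held Il6, a cytokine linked to muscle wasting, at 119 against 11.3 CPM (3.39, 2.13 to 5.03) and Ccl2 at 251.5 against 49.9 CPM (2.33, 1.71 to 3.03). In endothelial-like cells the median was −2.88 (8 measured), with Il1b at 2.29 against 285 CPM (−6.96), a level that lung NK-like cells also held at 345 CPM, and Il6 at 124 CPM in muscle with no lung count (log2 ratio 3.46 or higher, against the floor of 3 counts). The macrophage-like and cDC2-like medians turned direction under alternatives, up to 0.15 and down to −0.39.

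Lipid-associated macrophage genes as a list were lower in muscle neutrophil-like cells (median −1.91, 3 apart). The medians of 0.93 in macrophage-like (100.0th percentile, mean 0.29, 9 measured, 1 apart toward muscle and 1 toward lung), −0.99 in monocyte-like (0.120th) and −0.53 in cDC2-like cells (2.80th) were not called. Apoe, a lipid carrier, stood at 48979.8 against 23853 CPM in macrophage-like cells (1.04, 1.00 to 1.07) and at 2570 against 1689 CPM in monocyte-like cells (0.61, 0.52 to 0.69). Arg1 stood at 36.0 against 1071 CPM in macrophage-like (−4.89, −6.11 to −3.91) and 30.5 against 2212 CPM in monocyte-like cells (−6.18, −6.99 to −5.48). Spp1 stood at 1847 against 971 CPM in macrophage-like (0.93, 0.74 to 1.12) and 4.98 against 326 CPM in neutrophil-like cells (−6.03, −11.34 to −3.55). In endothelial-like cells the median was 0.59 (72.0th percentile, mean −1.04), with Lpl, the lipase of capillary walls, at 1143 against 75.0 CPM (3.93, 3.30 to 4.64). The cDC2-like median ran from −1.23 to 0.39 over the alternatives.

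MHC class II genes as a list were higher in muscle macrophage-like (median 1.57, 100.0th percentile, 6 measured, 1 apart) and monocyte-like cells (0.71, 99.88th, 7 measured, none apart by size). The cDC2-like median of 0.40 (95.1st, 7 measured, none apart) was not called. H2-Aa, an MHC class II alpha chain, stood at 4311 against 1058 CPM in macrophage-like (2.03, 1.88 to 2.18), 2696 against 1608 CPM in monocyte-like (0.75, 0.66 to 0.83) and 8507 against 6285 CPM in cDC2-like cells (0.44, 0.38 to 0.50). Cd74, the invariant chain, stood at 11738 against 4224 CPM in macrophage-like (1.47, 1.39 to 1.56) and 8342 against 5084 CPM in monocyte-like cells (0.71, 0.67 to 0.76), and Ciita, the master activator of these genes, at 70.0 against 172 CPM in cDC2-like cells (−1.30, −1.76 to −0.84). In neutrophil-like cells the median was −2.55 (7 measured, 4 apart, not called) and in endothelial-like cells −3.11 (6 measured, 2 apart), with lung Cd74 at 596 and 502 CPM. Lung T-like and NK-like cells, which normally lack it, held Cd74 at 748 and 471 CPM. Part of this lay in a sub-cluster of 89 cells with Cd74 at 1821 CPM, against 590.6 CPM in the other sub-clusters. These levels were therefore not shown to be free RNA alone. The monocyte-like median turned to −0.26 under alternatives, while the macrophage-like median ran from 0.10 to 1.62.

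Resident macrophage genes as a list were higher in muscle cDC2-like cells (median 2.45, 99.99th percentile, 5 measured, 3 apart). The monocyte-like median of 0.75 (98.975th, 9 measured) was not called. F13a1, coagulation factor XIII A of tissue macrophages, stood at 184 against 9.07 CPM in cDC2-like (4.34, 2.97 to 6.23) and 1005 against 436 CPM in monocyte-like cells (1.21, 1.06 to 1.34). Cd163, the haemoglobin scavenger receptor, stood at 66.9 against 2.27 CPM in cDC2-like (4.88, 2.36 to 10.20) and 78.1 against 8.88 CPM in monocyte-like cells (3.14, 2.47 to 3.80). In macrophage-like cells the median was −0.91 (0.25th percentile, 9 measured, none apart, not called), with Mrc1, the mannose receptor, at 1315 against 3229 CPM (−1.30, −1.48 to −1.12), Pf4 at 2076 against 5230 CPM (−1.33, −1.48 to −1.19) and Selenop, a selenium carrier, at 4878 against 2044 CPM (1.26, 1.13 to 1.38). The median was −0.12 in neutrophil-like (64.9th) and −1.38 in endothelial-like cells (0.675th). The macrophage-like median turned to 1.44 under alternatives.

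No interferon response median was called. The list had a median of 0.44 in cDC2-like cells (98.1st percentile, 11 measured, 1 apart), with Cxcl10, a CXCR3 ligand, at 173.5 against 29.5 CPM (2.56, 1.75 to 3.49) and Psmb8, an immunoproteasome subunit, at 211 against 453 CPM (−1.10, −1.37 to −0.83). In neutrophil-like cells the median was −1.28 (0.320th, 14 measured, 2 apart), with the antiviral gene Rsad2 at 4.98 against 119 CPM (−4.58, −9.88 to −2.09) and Irf1, a transcription factor, at 169.5 against 61.8 CPM (1.46, 0.90 to 1.96). It was −0.02 in monocyte-like (15.6th), −0.30 in macrophage-like (35.7th) and −0.39 in endothelial-like cells (3.30th), where Iigp1, an interferon-induced GTPase, stood at 327 against 124 CPM (1.40, 0.90 to 1.95). The cDC2-like median turned to −0.45 under alternatives, and the neutrophil-like median came as near to 0 as −0.11.

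Cachexia-linked secreted factors had medians of −0.93 in macrophage-like (0.710th percentile, 8 measured, 3 apart), −0.38 in monocyte-like (7.46th), −0.19 in cDC2-like (37.5th), 0 in neutrophil-like (58.3rd) and 0.77 in endothelial-like cells (93.9th). Gdf15, an appetite-suppressing hormone, stood at 176 against 64.7 CPM in macrophage-like cells (1.44, 0.74 to 2.14), and Osm, an interleukin 6 family cytokine, at 22.5 against 274 CPM (−3.60, −5.25 to −2.35). Inhba stood at 34.9 against 206 CPM in neutrophil-like cells (−2.56, −3.88 to −1.52). The macrophage-like median ran from −3.60 to 0.57 over the alternatives. Chemokine receptor and egress genes had medians of 0.08 in neutrophil-like (86.3rd), −0.05 in monocyte-like (42.9th), 0.19 in macrophage-like (90.4th), −0.24 in cDC2-like (34.8th) and −2.08 in endothelial-like cells (0.180th, 4 measured). Cxcr4, a receptor of marrow retention, stood at 658 against 334 CPM in neutrophil-like cells (0.98, 0.71 to 1.23), and Ccr2, the receptor of monocyte egress, at 493 against 219.9 CPM in cDC2-like cells (1.17, 0.86 to 1.49).

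Cell cycle genes had a median of −5.003 in endothelial-like cells (11 measured, 2 apart), with Stmn1, a microtubule regulator, at 16.8 against 154 CPM (−3.19, −3.77 to −2.59) and Pclaf, a replication factor, at 0.765 against 116 CPM (−7.25, −9.60 to −5.57). It was 0.48 in cDC2-like (96.5th), −0.36 in monocyte-like (3.26th) and 0 in neutrophil-like cells (47.3rd). T cell lists were read at low counts. Naive and central memory genes had medians of −0.96 in cDC2-like (3.46th, 3 measured) and 0 in monocyte-like (34.45th) and neutrophil-like cells (37.35th). Tissue-resident T cell genes had medians of −0.92 in neutrophil-like (5th), −0.38 in cDC2-like (30.5th) and −0.35 in monocyte-like cells (16.9th), with Rgs1, a regulator of G protein signalling, at 4.98 against 158.5 CPM in neutrophil-like cells (−4.99, −10.30 to −2.51). Cytotoxic effector genes reached 3 measured members only in neutrophil-like cells, with a median of 0 (38.0th).

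Dissociation stress genes, the immediate early and heat shock genes that tissue digestion induces, had a median of 1.70 in endothelial-like cells (99.7th percentile, 12 measured, 5 apart). There Hspa1a, a heat shock protein, stood at 754 against 60.0 CPM (3.65, 2.95 to 4.46) and Zfp36, an early response RNA-binding protein, at 1665 against 217 CPM (2.94, 2.56 to 3.34). The median was 0.40 in cDC2-like (99.0th), 0.19 in macrophage-like (97.6th), −0.05 in neutrophil-like (80.4th) and −0.13 in monocyte-like cells (66.5th). Myofibre genes as a list were called higher in muscle in every class, though few members were apart by size in leukocytes. The medians were 4.30 in endothelial-like (11 measured, 9 apart), 5.52 in monocyte-like (6, 1 apart), 4.37 in neutrophil-like (4, 1 apart), 4.09 in macrophage-like (8, 1 apart) and 1.39 in cDC2-like cells (8, 2 apart). Myh4, the fast IIb myosin heavy chain, stood at 149.5 CPM in muscle neutrophil-like cells with no lung count (log2 ratio 8.25 or higher, against the floor of 3 counts), and Acta1, skeletal actin, at 1125 CPM in muscle endothelial-like cells (6.64 or higher). Erythroid genes had a median of 2.76 in endothelial-like cells, with the globin Hbb-bs at 422 CPM in muscle and none in lung (5.23 or higher). Fibroblast genes had medians of −2.01 in endothelial-like (6 measured), −0.48 in monocyte-like and −0.51 in neutrophil-like cells, with the proteoglycan Dcn at 178 against 11.2 CPM (3.99) and Col1a2, a collagen I chain, at 10.2 against 149.9 CPM (−3.88) in endothelial-like cells. Endothelium genes had a median of 0.03 in endothelial-like cells (Pecam1 1277 against 742 CPM, 0.78), and lung epithelium genes −1.10 in monocyte-like and 0 in neutrophil-like cells, where keratin Krt18 stood at 44.7 CPM in lung and none in muscle.

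**Figure D3:**
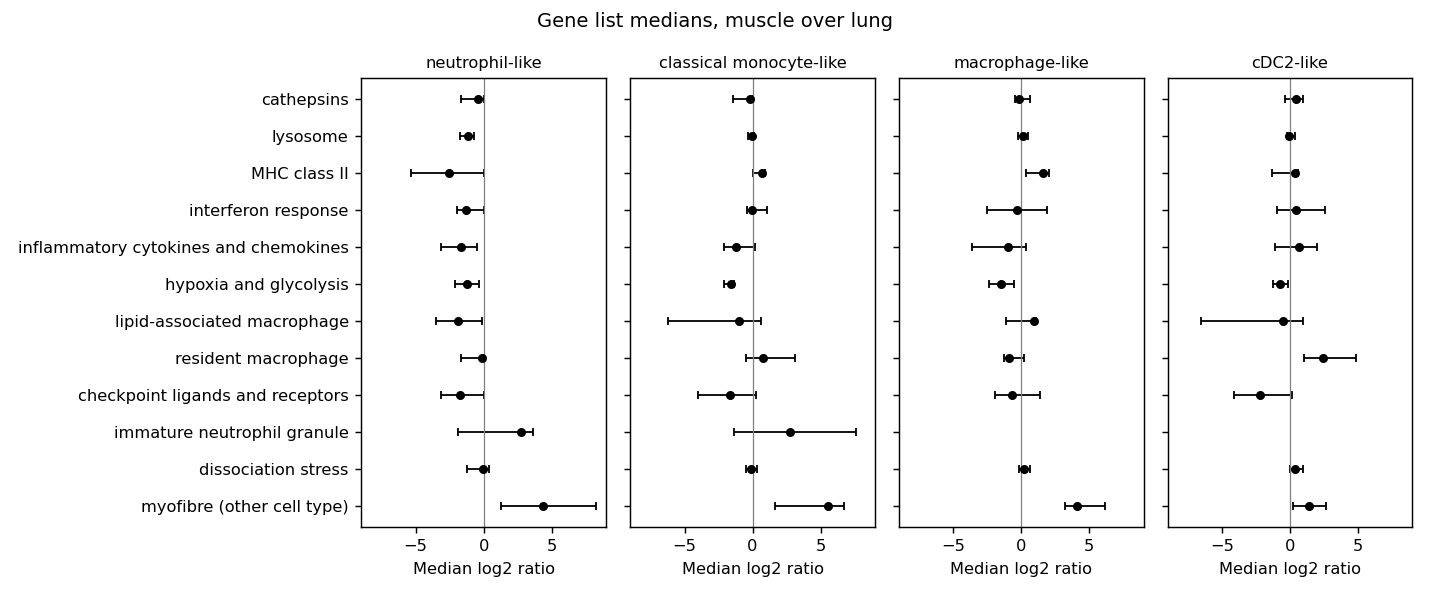
Median log2 ratio of muscle over lung (x axis) for 12 gene lists in neutrophil-like, classical monocyte-like, macrophage-like and cDC2-like cells (4 panels), with bars for the 95% interval of the median over members and a line at 0. Where too few members were measured for such an interval the bars are their full range. Hypoxia and glycolysis genes lay left of 0 in all panels (−1.26, −1.56, −1.46 and −0.71).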

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

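All tests in this part were chosen after the result they address was seen. Results are listed here because a signal appeared in data outside the report's comparisons, above what a count of 0 allows. Xist, the RNA of the inactive X chromosome, stood at 759 CPM (721 to 798) in 59 lung epithelial-like cells of cluster 30 and at 3889 CPM (3710 to 4074) in 26 lung cells of unnamed cluster 36. Rag1, a recombinase of developing lymphocytes, stood at 1318 CPM (941 to 1794) in 13 lung cells of T-like sub-cluster 13. The myofibre genes together stood at 2480 CPM (2435 to 2526) in the 3301 muscle barcodes over the mitochondrial limit, against 1455 CPM in kept muscle cells, with Ptprc at 27.6 CPM against 162 CPM.

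Most kept muscle cells lay outside the leukocyte classes although the gate was CD45. Removal of leukocytes by the mitochondrial limit was argued against, since without the limit the leukocyte share was 10.3%, below the 15.3% with it. Misnaming was argued against by Ptprc at 3.60 CPM in the other muscle classes, against 554 CPM in muscle leukocytes. Carry-over of unselected cells by the beads, which would leave the 83.8% seen, cannot be told apart from other origins without an unselected library. No biological explanation was tested.

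Cluster 30 carried Xist with 1 count over the 4 Y-linked genes (0.498 CPM). The 4 Y-linked genes had an upper bound of 2.78 CPM there, against 185 CPM in lung leukocytes, which is consistent with epithelial cells of another sex than the leukocytes. Pooling of mice of both sexes was argued against by Xist at 3.30 CPM in lung leukocytes, and doublets with leukocytes by Ptprc at 2.99 CPM, against 535 CPM in lung leukocytes. Cluster 36, with a Y-linked upper bound of 19.1 CPM, and epithelial-like cluster 11, with Xist at 87.5 CPM and Y-linked genes at 25.3 CPM, were left open. An implanted line or another animal as their origin was not tested, and the labels name neither.

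Ctsl was lower in muscle than in lung neutrophil-like cells. A different mix of clusters was argued against by −2.11 within cluster 9, and free RNA of lung macrophages by 42.7 CPM in lung B-like cells, against 322 CPM in lung neutrophil-like cells. With cells thinned the log2 ratio was −2.13, but this alters the weight of each cell and not its expected CPM, so depth per cell was left unweighed. The tissue itself remained open and untested, since each tissue was 1 library.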

How the results depend on the processing

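No paired analysis was possible because each tissue had 1 library, and the shared replicate number 1 pairs nothing. Of 911 alternative values for single-gene log2 ratios 652 stayed within the main interval and 259 lay outside it, and 66 had the opposite sign. None of those 66 was for a gene apart by size, the only ones counted as reversed. Of 1234 for list medians 1119 stayed, 110 moved and 5, of called lists, reversed, while 133 in all had the opposite sign. For lists with few measured members the main interval was their full range, so staying within it says little about stability. Further, of 577 levels 382 stayed and 195 moved, and of 342 shares 186 stayed and 156 moved. Of 153 counts, which were of genes apart by size and of classes compared, 91 stayed and 62 moved. The hypoxia and glycolysis median stayed below 0 in all 4 leukocyte classes under every alternative. The limits of 25% and none, totals without mitochondrial and rRNA-like genes, 1 cluster per class, each gene without its highest cell and the minimum of 30 cells were chosen after seeing the data. The 1-cluster setting gave values only for endothelial-like, monocyte-like and neutrophil-like cells, and thinning and TMM gave none for shares. Its clusters, with Gng11, Cacna1d and Retnlg as first top genes, held 35 of 1212, 38 of 71 and 42 of 57 muscle cells. The Cacna1d cluster held less Plac8 and more Malat1 than the other monocyte-like cluster, so its values do not stand for the whole class. Depth limited low levels, since the floor of 3 counts stood at 14.95 CPM in muscle neutrophil-like and 13.5 CPM in muscle macrophage-like cells. Subtraction of the B-like level rested on 4 muscle cells, with no Ctsl count to take off there, and gave no Cd274 ratio. For each value below that moved or reversed the cause was not tested, except that thinning, a lower ratio and no minimum count alter what can be called.

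The leukocyte share of muscle (15.3%) was 11.5% at a limit of 25%, 21.9% at 5% and 10.3% with none. That of lung (92.9%) was 88.4% at resolution 2.0, 76.6% at 5%, 87.3% with doublets removed at double the share, 81.9% with libraries clustered alone, 85.4% with at least 500 genes, 87.2% with no doublet removal and 92.1% with no limit. The neutrophil-like share of lung leukocytes (39.4%) was 40.6%, 43.6%, 34.4%, 35.0% and 33.9% at resolution 2.0, 5%, double doublets, libraries alone and no doublet removal.

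Ctsl in muscle fibroblast-like cells (1008 CPM) was 1076 with TMM, 885 at 25%, 1224 at 5%, 814 thinned, 897 with no doublet removal, 855 with no limit and 1128 with totals without mitochondrial and rRNA-like genes. In lung macrophage-like cells (1297 CPM) it was 551 at resolution 2.0, 686.2 at 25%, 783 at 5%, 623 with double doublets, 854.5 with libraries alone, 728 with at least 500 genes, 524 with no doublet removal, 685.75 with no limit and 1424 with the reduced totals. The macrophage-like Ctsl log2 ratio (−0.24) was 0.58 at resolution 2.0, 0.064 at 25%, 0.18 at 5%, 0.36 with double doublets, −0.82 without the highest cell, 0.31 with libraries alone, −0.75 thinned, 0.14 with at least 500 genes, 0.52 with no doublet removal and 0.45 with no limit. The Cd274 log2 ratio of neutrophil-like cells (−1.77) was −1.31 in 1 cluster.

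The MHC class II median of monocyte-like cells (0.71) reversed to −0.25 in 1 cluster, −0.26 at resolution 0.5, −0.25 at 25% and −0.21 with no limit. The dissociation stress median of cDC2-like cells (0.40) reversed to −0.016 with libraries alone. The hypoxia median of monocyte-like cells (−1.56) was −2.20, −2.18, −2.44 and −2.70 in 1 cluster, at resolution 0.5, at 25% and with no limit. The granule median of neutrophil-like cells (2.73) was 3.62 at 5%.

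Genes higher in lung in monocyte-like cells (94) numbered 173 in 1 cluster, 169 at resolution 0.5, 213 at 25%, 41 thinned, 249 with no limit and 497 at a ratio of 2. In endothelial-like cells (91) they numbered 31 in 1 cluster, 28 with double doublets, 40 without the highest cell, 5 thinned, 682 with no minimum count and 316 at a ratio of 2. In neutrophil-like cells (155) they numbered 32 in 1 cluster, 233 without the highest cell, 43 thinned and 937 at a ratio of 2. Genes higher in muscle in monocyte-like cells (64) numbered 154 with double doublets, 39 without the highest cell, 24 thinned, 315 with no minimum count and 374 at a ratio of 2. In endothelial-like cells (261) these were 123 in 1 cluster, 417 without the highest cell, 81 thinned and 1113 at a ratio of 2. In neutrophil-like cells (43) these were 9 in 1 cluster, 27 without the highest cell, 22 thinned, 213 with no minimum count and 160 at a ratio of 2.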

Other observations

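Lung T-like and NK-like cells split into subsets when the 946 cells of both libraries were clustered alone. Regulatory-like cells formed 2 sub-clusters, 1 of 131 lung cells with Foxp3, the regulatory T cell factor, at 485 CPM (421 to 557) and Ctla4 at 980.0 CPM, and 1 of 72 lung cells with Foxp3 at 418 CPM (342 to 506), Ctla4 at 1497 CPM, the interleukin 33 receptor Il1rl1 at 924 CPM (809 to 1051) and Areg, a repair growth factor, at 637 CPM (542 to 744). A sub-cluster of 105 lung cells held Cd8a at 843 CPM (762 to 931) with Pdcd1 at 360.3 CPM (308 to 419), Lag3 at 311 CPM, Tigit at 317 CPM and the chemokine Ccl1 at 1394 CPM (1288 to 1505). Cd8a was also read in 49.05% of the NK-like class, at a class-wide level of 565 CPM. NK receptors marked a sub-cluster of 50 lung cells with the killing protease Gzma at 8711 CPM (8225 to 9217), the receptor Ncr1 at 421 CPM (319 to 544) and no count of Cd3e. A sub-cluster of 36 lung cells held Il17a at 1131 CPM (940.2 to 1349.7) and Trdc, the gamma-delta receptor constant gene, at 322 CPM, with no count of Cd4. A sub-cluster of 16 cells, 5 of them from muscle, held the neuropeptide gene Calca at 4184 CPM (3645 to 4781), Gata3 at 833 CPM and Il5 at 600.5 CPM (408 to 852) with 1 count of Cd3e, markers of group 2 innate lymphoid cells. A sub-cluster of 13 lung cells with Rag1 in 76.9% of them also held Cd4 at 593 CPM (351 to 937) and Cd8a at 527 CPM (301 to 856), and Dntt, the enzyme that adds nucleotides at receptor joins, at 593 CPM. Rag1 and Dntt stood at 97.4 CPM (59.5 to 150.5) and 112 CPM in the 28 cycling cells of another sub-cluster. Not all subsets were clean. A sub-cluster of 89 cells had Ccl6, Cst3 and H2-Aa among its top genes, with Cst3 at 1712 against 406.6 CPM in the others. In a sub-cluster of 37 cells Osm stood at 909 against 22.6 CPM and the neutrophil marker Hdc at 606 against 20.1 CPM. Both entered the T-like and NK-like levels read for free RNA.

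Muscle endothelial-like cells formed several clusters. A cluster of 413 muscle cells held Timp4 at 2317 CPM (2233 to 2404), Gpihbp1, the capillary anchor of lipoprotein lipase, at 3671 CPM (3565 to 3780), Thrsp, Kcna5 and C1qtnf9, with Ctsl at 799 CPM. A cluster of 61 cells held Selp, the venular P-selectin, at 4369 CPM (4133 to 4615) beside Tll1, Hrh1, Zfp423 and Gm38070, with Ctsl at 109 CPM. A cluster of 83 muscle cells held Fbln5, an elastic fibre protein, at 798 CPM (716 to 887) beside Pthlh, Stmn2, Gper1 and Alpl, with Ctsl at 264 CPM. Malat1, a nuclear RNA, stood at 3041, 14413 and 4128 CPM in these 3 clusters, and the largest endothelial-like cluster also held low Ctsl (122 CPM) with high Malat1 (12918 CPM), so the Selp cluster's Ctsl was not separated from RNA quality. Among fibroblast-like cells 47 muscle cells carried the tendon genes Fmod at 7221 CPM (6871 to 7583), Tnmd at 717 CPM and Thbs4 at 8948 CPM beside Angptl7 and Chad, with Ctsl at 1073 CPM, while a cluster of 118 muscle and 17 lung cells with Clec3b, Dpep1, Col3a1, Col1a1 and Lum held Ctsl at 1123 CPM. A fibroblast-like cluster of 100 muscle and 3 lung cells with C7, Dpyd, Itgbl1, Bnc2 and 4930578G10Rik held Ctsl at 87.5 CPM. Malat1 stood at 5931, 4794 and 24327 CPM in these 3 clusters, so RNA quality moved with Ctsl here too. Satellite-like cells with Myod1, the factor of activated muscle stem cells, at 739 CPM (593 to 911), Myf5, Chrdl2, Pax7 and Chodl held Ctsl at 983 CPM, against 232 CPM in the satellite-like cluster with Hs6st3, Calcr, Pax7, Erfe and Col19a1. Malat1 stood at 3814 and 16268 CPM and the median mitochondrial share at 4.59% and 6.92% in these 2 clusters, so RNA quality moved with the Ctsl contrast.

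Lung neutrophil-like cells lay in clusters that held few muscle cells. A cluster of 640 lung cells and 1 muscle cell carried Siglecf at 310.0 CPM (282 to 340), the collagenase Mmp9 at 1124 CPM (1070 to 1180), Cd177, Entpd3 and P2ry14. A cluster of 452 lung cells carried Ccl3 at 7907 CPM (7714 to 8103), Rab15, Mreg, Rps6ka2 and Fam71f2, with Ctsl at 489.99 CPM. Its name rested on 3 markers and a mean log2 fold of 0.54, just over the limit of 0.5, with Retnlg and Cxcr2 below their level in other cells. A cluster of 810 lung and 7 muscle cells carried Mirt2, G0s2, Acod1, Cxcl2 and Clec4e, with Ctsl at 288 CPM, and cluster 9, with most muscle cells, had Ctsl at 190.2 CPM. In lung, 59 epithelial-like cells of median 31375 UMIs carried Cldn3, a tight junction claudin, at 844 CPM (805 to 886), Mmp7 at 299.9 CPM, Apoa1, Igfbp1 and Rbp2, with the surfactant gene Sftpc at 1 count. Cluster 38, unnamed, held 20 muscle cells and 1 lung cell with Cdh19, a Schwann lineage cadherin, at 2878 CPM (2489 to 3312), Chl1, Cadm2, Grik2 and Gm20754.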
